A study of Homo sapiens with 20 samples.

How the data were processed

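RNA was measured by poly(A)-selected, strand-specific, paired-end RNA sequencing with reads of 100 bases in OPM2 cells, a human multiple myeloma line. There were 20 libraries in 10 groups of 2 independent biological replicates per the labels: a DMSO vehicle group, and for each inhibitor groups harvested at 2, 5 and 20 h. Panobinostat and romidepsin were used at 10 nM and ricolinostat at 100 nM. The ricolinostat dose is 100 nM in the sample titles, the treatment protocol and the study design, whereas the treatment field of the same samples gives 10 nM. The labels give no harvest time for the DMSO group and list the batch as unknown.

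The deposited table holds raw read counts per Ensembl gene and library, made by the authors with HISAT2, SAMtools and featureCounts on GRCh38 per the submitters' processing notes. All values tested were whole numbers of 0 or more. The annotation release, the strand setting and whether reads or read pairs were counted are not given in the sources used here. Counts of antisense genes therefore rest on an unknown strand setting, and counts of near-identical copies such as HSPA1A and HSPA1B on an unknown rule for shared reads. Total counts per library ran from 17264640 to 29088868.

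Of the 78932 gene identifiers, 61481 were found in the name table and 42179 of these had a symbol, while 57356 were found in GENCODE 29, which gave gene types and positions. Symbols shared by several identifiers numbered 322. The filterByExpr filter of edgeR 4.0.16 (minimum count 10, 10 groups) left 20957 genes for testing. Counts were scaled by TMM and fitted in 1 robust quasi-likelihood model with a term per group, in R 4.3.3. The common dispersion was 0.00175, a biological coefficient of variation of 0.0419. Fold changes are log2 values from edgeR with a standard error, and levels are CPM, the cpm values of edgeR. Adjusted p-values are those of the two-sided edgeR quasi-likelihood F test after Benjamini-Hochberg correction within each contrast, with a threshold of 0.05. A gene that passed is said to be higher, lower, risen, fallen or changed. The contrasts were 9 of an inhibitor with DMSO, 9 between inhibitors at the same time and 6 between successive times of an inhibitor.

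For a gene with 0 counts in both libraries of a group, fold changes are lower bounds against a floor of 3 counts over the group's 2 libraries. With 1 to 3 counts a ratio with its 95% counting interval is given in place of the fitted value. Such intervals and floors cover counting error only.

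The contrasts, lists and rule for named genes were fixed before the data were examined. Named was a fixed panel, with CDKN1A, MYC, IRF4, PRDM1, IKZF1, NSD2, FGFR3, CCND2, BCL2L11, MCL1, HDAC1, HDAC6, TUBB3 and HSPA1A in every contrast with DMSO. To these were added, per contrast, the 5 largest rises and falls with DMSO and between inhibitors, and 3 between times, among protein-coding genes that passed the test, reached a mean of 5 CPM in a group and did not overlap between libraries. Up to 4 members of each list with the largest changes and at least 5 CPM were also eligible. Some of the genes named by these rules are not reported here.

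There were 27 pathway lists: HDAC enzymes, polyadenylated histones, CDK inhibitors and p53 targets, mitosis, DNA replication, ribosome biogenesis, ribosomal proteins, plasma cell and myeloma genes, unfolded protein response, integrated stress response, heat shock, pro-apoptotic and anti-apoptotic families, MHC class I, MHC class II, interferon-stimulated genes, NF-kB targets, immediate-early genes, sterol synthesis, tubulins, metallothioneins, acetyltransferases and acetyl-lysine readers, autophagy and lysosome, proteasome, nuclear oxidative phosphorylation, mitochondrially encoded mRNAs and neuronal genes. A further 6 lists held markers of T and NK, myeloid, erythroid, early B, stromal and epithelial cells. Lists with at least 5 tested genes were tested by camera (limma 3.58.1, preset correlation 0.01), which compares a list with all other genes. Its p-values were adjusted over the 243 tests of lists and contrasts with DMSO, and over the 243 between inhibitors. Camera was also run with an estimated correlation. With DMSO, 123 of the 243 list tests passed with the preset correlation and 45 of these also with an estimated one; between inhibitors 119 and 60 did.

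The DMSO libraries are shared by all contrasts with DMSO and could not be divided between inhibitors without leaving single libraries. Overlaps were therefore set beside the number expected from independent calls and beside 5 simulations of unchanged groups sharing the controls. The method was also tested on simulated data for panobinostat at 20 h, with 200 genes changed. After the filter 19028 genes were left, 18842 of them unchanged, and a changed gene that the filter removed counts as not recovered. Of genes changed 1.5-, 2- and 4-fold, 50.7%, 58.2% and 69.7% were recovered, and 91.7%, 94.1% and 100% of those at 5 CPM or more. Of the unchanged genes 15 were called, which was 11.2% of the calls, above the nominal 5%, and 4.76% had an unadjusted p under 0.05. Camera called the list made of changed genes and also 2 of 27 other lists, which may hold changed genes by chance. In the data 15329 genes were called in this contrast. The simulation, with 200 genes changed, therefore did not test the scaling where most genes change.

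Alternatives were DESeq2-type size factors (RLE), library size as the only scaling, the DESeq2 1.42.0 Wald test, no filter on low counts, a block for replicate number, a fit of the 2 compared groups alone, camera with an estimated correlation, fry in place of camera, and each library left out in turn. Where a library is left out, the lone library of its group is assumed to vary like the other groups. Replicate numbers did not pair the libraries: over 45 pairs of groups and 9179 genes, correlations between replicate differences ran from -0.0961 to 0.0961. No library was excluded.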

Results

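Transcript levels were measured in 20 RNA-seq libraries of OPM2 cells, a human multiple myeloma line: 2 given DMSO and 2 for each of 3 histone deacetylase (HDAC) inhibitors at each of 2, 5 and 20 h. Panobinostat and ricolinostat are hydroxamic acids and romidepsin is a cyclic depsipeptide. Panobinostat and romidepsin were given at 10 nM and ricolinostat at 100 nM, so that ricolinostat is compared at another dose. Total counts were 25313510 and 28656570 in the DMSO libraries and ran from 17264640 to 29088868 over all libraries. Of 20957 genes tested, the first principal component held 63.1% of the variance and the second 8.93%. Unless stated otherwise, changes are log2 fold changes ± SE from the edgeR quasi-likelihood fit with n = 2 libraries per group, and p-values are adjusted by Benjamini-Hochberg.

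The comparison of panobinostat with DMSO asks which transcripts differ with this inhibitor and how soon. The labels give DMSO no harvest time, so in all contrasts with DMSO time in culture cannot be separated from the inhibitor. Genes that define plasma cells and myeloma fell from 2 h on. MYC, a transcription factor of growth (ENSG00000136997, GRCh38 chromosome 8, 127735434 to 127741434), changed by -2.88 ± 0.05, -3.60 ± 0.05 and -5.52 ± 0.06 at 2, 5 and 20 h (adjusted p = 1.6e-92 at 20 h). Its level went from 440 ± 11.3 CPM in DMSO to 9.53 ± 1.02 CPM at 20 h (SD, n = 2). PRDM1, a plasma cell transcription factor (ENSG00000057657, chromosome 6, 106086320 to 106109939), changed by -1.74 ± 0.04, -2.96 ± 0.05 and -5.88 ± 0.06. TNFRSF17, which encodes the BCMA receptor (ENSG00000048462, chromosome 16, 11965107 to 11968068), reached -8.18 ± 0.09 at 20 h.

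Of the 29 measured plasma cell and myeloma genes, 22, 24 and 26 fell and 2, 2 and 3 rose with panobinostat at 2, 5 and 20 h, the same numbers adjusted over the list alone, and 5, 3 and 0 did not pass. The camera test gave adjusted p = 2.8e-18, 2.4e-19 and 2.5e-19, with medians of -0.64, -1.12 and -2.92. IRF4, on which myeloma cells depend, changed by -0.26 ± 0.03, -1.02 ± 0.03 and -2.46 ± 0.04, and IKZF1, a lymphoid zinc finger factor, by -0.73, -1.91 and -4.82 ± 0.07. CCND2, a G1 cyclin, changed by -1.07, -2.31 and -4.63 ± 0.05. FGFR3, a receptor tyrosine kinase (ENSG00000068078, chromosome 4, 1793293 to 1808872), changed by -1.12, -2.11 and -3.77 ± 0.04 from 3535 ± 23.0 CPM in DMSO (SD, n = 2). NSD2, a histone methyltransferase on the same chromosome, changed by -0.74, -1.12 and -1.52 ± 0.03. At 20 h POU2AF1, a B cell coactivator, reached -7.30 ± 0.07, CD28 -7.01 ± 0.09 and MZB1, a chaperone of antibody secretion, -6.91 ± 0.11. Immunoglobulin genes held 0.449% of counts in DMSO and 0.00784% with panobinostat at 20 h.

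Cell division genes fell as well. Of 33 mitosis genes 23, 28 and 31 fell and 2, 3 and 1 rose with panobinostat at 2, 5 and 20 h, also when adjusted over the list alone (camera adjusted p = 5.6e-09, 3.5e-12 and 3.8e-14). At 2 h the call was lost (adjusted p = 0.078 with an estimated correlation). At 20 h FOXM1 changed by -2.68 ± 0.05, UBE2C by -2.61 ± 0.06, AURKA by -2.47 ± 0.06 and PLK1 by -2.30 ± 0.05. Of 43 DNA replication genes 28 fell and 8 rose at 5 h (28 and 9 adjusted over the list alone; camera adjusted p = 1.4e-04). At 20 h 36 fell and 4 rose, also adjusted over the list alone (adjusted p = 4.3e-08). Both calls were lost, with adjusted p = 0.25 and 0.088 with an estimated correlation. At 20 h TYMS, which makes thymidylate, reached -4.33 ± 0.08 and MCM5, a replicative helicase subunit, -2.36 ± 0.04. CDKN1A, the CDK inhibitor p21, rose by 0.88 ± 0.05, 1.15 ± 0.05 and 2.52 ± 0.05, from 54.8 to 315 CPM at 20 h. In the list of CDK inhibitors and p53 targets, 18 of 28 genes rose and 4 fell at 2 h (19 and 6 adjusted over the list alone; camera adjusted p = 6.1e-06), with CDKN2B at 2.80 ± 0.10. At 5 h 18 rose and 7 fell, also adjusted over the list alone (adjusted p = 6.1e-04; adjusted p = 0.07 with an estimated correlation), and at 20 h the list did not pass (adjusted p = 0.078).

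Ribosome biogenesis genes fell later. Of 40 genes, 15 rose and 17 fell with panobinostat at 2 h, also adjusted over the list alone (adjusted p = 0.9). At 5 h 8 rose and 26 fell, also adjusted over the list alone (1.7e-07; adjusted p = 0.15 with an estimated correlation). At 20 h 35 fell and 1 rose (36 and 1 adjusted over the list alone; 3.9e-14), with WDR12 at -2.70 ± 0.05. Of 41 nuclear oxidative phosphorylation genes 35 fell and 4 rose at 20 h, also adjusted over the list alone (camera adjusted p = 3.0e-08; adjusted p = 0.18 with an estimated correlation), with NDUFA6 at -1.94 ± 0.06. Of 31 proteasome subunits 23 fell and 4 rose at 20 h, also adjusted over the list alone (4.4e-05; adjusted p = 0.31 with an estimated correlation), with PSMD7 at -2.22 ± 0.05. Genes with symbols starting with MT-, a set not limited to mRNAs, held 4.55% ± 0.198 of counts in DMSO and 6.34% ± 0.372 at 20 h (SD, n = 2). These are shares of raw counts, without TMM scaling.

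Chaperones rose at 2 h. HSPA1B, an inducible HSP70 (ENSG00000204388, chromosome 6, 31827735 to 31830255), rose by 5.01 ± 0.09, 4.56 ± 0.09 and 2.73 ± 0.09, and its near-identical neighbour HSPA1A by 5.03 ± 0.23, 4.31 ± 0.24 and 2.66 ± 0.27. Of 21 heat shock genes 14 rose and 1 fell at 2 h, also adjusted over the list alone (camera adjusted p = 6.2e-08). At 20 h 5 rose and 14 fell, also adjusted over the list alone (adjusted p = 0.021; adjusted p = 0.31 with an estimated correlation). HSPA8, the constitutive HSP70, rose by 1.32 ± 0.03 at 2 h and changed by -1.14 ± 0.03 at 20 h. Sterol synthesis genes rose at 2, 5 and 20 h, with 17, 16 and 15 of 24 higher and 4, 5 and 8 lower (17, 16 and 15 higher and 4, 6 and 8 lower adjusted over the list alone). Camera gave adjusted p = 1.0e-09, 8.6e-05 and 0.026, and at 20 h adjusted p = 0.2 with an estimated correlation. INSIG1, a feedback regulator of sterol synthesis, reached 3.55 ± 0.04 and IDI1 2.65 ± 0.05 at 20 h. Autophagy and lysosome genes rose at 2 h, 15 of 27 against 3 lower (16 and 4 adjusted over the list alone; camera adjusted p = 1.2e-05). At 5 h 18 rose and 5 fell, also adjusted over the list alone (8.4e-04; adjusted p = 0.075 with an estimated correlation). NEU1, a lysosomal sialidase, rose by 1.41 ± 0.05 and 2.50 ± 0.04.

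Immediate-early genes rose throughout, with 17, 18 and 21 of 27 higher and 6, 5 and 5 lower at 2, 5 and 20 h, also adjusted over the list alone. Camera gave adjusted p = 4.3e-04, 6.7e-04 and 5.4e-06 (adjusted p = 0.07, 0.075 and 0.031 with an estimated correlation). EGR1 reached 5.93 ± 0.23 and the nuclear receptor NR4A2 4.47 ± 0.13 at 20 h. Of 31 interferon-stimulated genes 8, 18 and 21 rose and 0, 3 and 4 fell, also adjusted over the list alone. Camera gave adjusted p = 0.025, 0.0048 and 0.033 (adjusted p = 0.073, 0.036 and 0.08 with an estimated correlation). OASL rose by 2.23 ± 0.17, 4.47 ± 0.14 and 5.22 ± 0.13. MHC class I genes fell at 20 h, 14 of 19 against 4 higher, also adjusted over the list alone (adjusted p = 3.1e-05), with PSMB10 at -5.46 ± 0.14, whereas MICA, an NKG2D ligand, rose by 3.45 ± 0.23.

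TUBB3, neuronal tubulin (ENSG00000258947, chromosome 16, 89921392 to 89938761), rose by 4.36 ± 0.34, 6.57 ± 0.25 and 9.27 ± 0.20, from 0.154 ± 0.0982 CPM in DMSO to 101 ± 1.13 CPM at 20 h (SD, n = 2). Of 16 measured neuronal genes 3, 11 and 14 rose and 0, 1 and 1 fell (3, 12 and 14 higher adjusted over the list alone). The list passed at 5 h (camera adjusted p = 0.0016) and 20 h (1.4e-05). Its median at 20 h was 5.62, or 5.43 with genes at 0 counts in a group taken at their bound. SYT11, a synaptotagmin, rose by 7.58 ± 0.14 at 5 h and 10.34 ± 0.11 at 20 h. At 20 h the adhesion molecule L1CAM was at least 194-fold higher, the intermediate filament NES at least 941-fold higher and the p53 relative TP63 at least 539-fold higher than in DMSO, where they had 0 counts. All 3 measured metallothioneins rose at each time, also adjusted over the list alone, with MT2A at 4.01 ± 0.19, 5.55 ± 0.17 and 7.92 ± 0.16, a list too short for camera.

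Other rises with panobinostat at 2 h included TMEM169, 5.28 ± 0.40, and SLC2A4, an insulin-responsive glucose transporter, 5.15 ± 0.32. Falls at 2 h included OSM, the cytokine oncostatin M, -3.95 ± 0.27, and the chemokine receptor CCR1, -3.59 ± 0.06. At 5 h OSM was at -4.96 ± 0.32 and MGAT3, a glycosyltransferase, at -4.18 ± 0.06. At 20 h TASL reached -9.57 ± 0.19, and CCR2 fell by a ratio of 381 (95% counting interval 105 to 3150). Among apoptosis genes, BCL2L11, which encodes BIM, rose by 1.07, 1.31 and 0.63 (SE 0.06), and MCL1, a survival protein, by 0.84 and 0.58 at 2 and 5 h, with 0.01 ± 0.04 at 20 h (adjusted p = 0.72). BBC3, which encodes PUMA, rose by 2.72, 2.89 and 4.32 ± 0.22. HDAC6, the cytoplasmic deacetylase, changed by -0.40, -0.34 and 1.17 ± 0.06, and HDAC1 by -0.04 (adjusted p = 0.53), -0.16 and 0.23 ± 0.04.

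In all, 4353, 6443 and 8560 genes were higher and 3799, 5422 and 6769 lower with panobinostat at 2, 5 and 20 h; 1277, 3682 and 6183 rose and 861, 1817 and 3739 fell at least 2-fold. With library size as the only scaling the median change of all genes moved from 0.12 to 0.25 at 5 h and from 0.25 to 0.56 at 20 h, and the higher share of calls at 20 h from 55.8% to 65.9%. With that scaling MCL1 at 20 h passed (0.32), HDAC1 at 5 h did not (-0.02), and the heat shock and interferon calls at 20 h ended (adjusted p = 0.089 and 0.079). The replicates at 2 h of panobinostat differed more than those of other groups (chi-square per degree of freedom 6.48, others 2.35 to 4.25). The higher share of calls at 2 h moved from 53.4% to 44.0% without panobinostat 2 h replicate 2, to 47.1% with DESeq2-type size factors and to 47.3% with the DESeq2 test. Without 1 library, HDAC1 at 5 h was lost (-0.13 without panobinostat 5 h replicate 1), as was sterol synthesis at 20 h (adjusted p = 0.0502 without DMSO replicate 1).

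**Figure D1:**
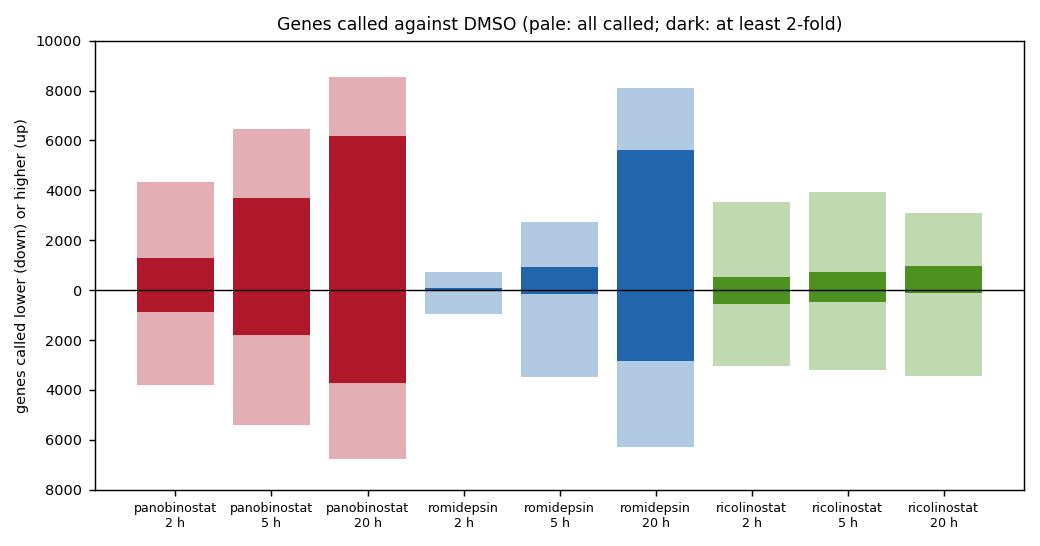
Number of genes called higher (upwards) and lower (downwards) than DMSO at 2, 5 and 20 h of each inhibitor (edgeR, adjusted p below 0.05, n = 2 libraries per group). Panobinostat runs from 4353 higher genes at 2 h to 8560 at 20 h and romidepsin from 743 to 8095, while ricolinostat stays between 3082 and 3935.

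Romidepsin, given at the same dose as panobinostat, asks the same question for a cyclic depsipeptide. Its changes were small at 2 h and large at 20 h. MYC changed by -0.91 ± 0.04, -1.46 ± 0.04 and -4.20 ± 0.05 at 2, 5 and 20 h, to 24.0 ± 0.767 CPM at 20 h (SD, n = 2), and IRF4 by -0.75, -0.92 and -1.36 ± 0.03. PRDM1 changed by -0.14 ± 0.04 (adjusted p = 0.015), -0.49 ± 0.04 and -2.67 ± 0.05. CDKN1A changed by -0.71 ± 0.06 at 2 h, -0.15 ± 0.06 at 5 h (adjusted p = 0.037) and 3.36 ± 0.05 at 20 h, when it reached 564 CPM.

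Of the 29 plasma cell and myeloma genes 16, 18 and 26 fell and 1, 1 and 3 rose with romidepsin (16, 18 and 26 lower and 3, 2 and 3 higher adjusted over the list alone). By camera the list had adjusted p = 3.8e-17, 4.2e-13 and 2.8e-18, with TNFRSF17 at -5.61 ± 0.07, MZB1 at -4.64 ± 0.08 and the syndecan SDC1 at -4.24 ± 0.05 at 20 h. FGFR3 changed by -0.46, -0.86 and -3.46 ± 0.04, CCND2 by -0.29, -0.73 and -2.77 ± 0.05 and NSD2 by -0.17, -0.27 and -0.65 ± 0.03. IKZF1 was at -0.06 at 2 h (adjusted p = 0.53), and fell to -0.19 at 5 h and -2.84 ± 0.05 at 20 h. Immunoglobulin genes held 0.0381% of counts at 20 h. HDAC6 changed by -0.19 (adjusted p = 0.028), -0.18 (0.012) and 0.98 ± 0.06, and HDAC1 by -0.08 (adjusted p = 0.31), -0.11 (0.052) and 0.27 ± 0.04.

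Immediate-early genes fell with romidepsin at 2 h, 11 of 27 against 2 higher (12 and 3 adjusted over the list alone; camera adjusted p = 1.8e-13). They rose at 20 h, 22 against 3 lower, also adjusted over the list alone (8.2e-11). At 5 h the list did not pass (adjusted p = 0.21). DUSP2, a MAP kinase phosphatase, changed by -1.32 ± 0.09, -2.00 ± 0.10 and 3.38 ± 0.07, and NR4A3 rose by 5.73 ± 0.23 at 20 h. Pro-apoptotic genes fell at 2 h, 3 of 13 against 0 higher, also adjusted over the list alone (adjusted p = 0.0011). BCL2L11 changed by -0.86, -0.40 and 1.78 ± 0.06. At 5 h 5 fell and 0 rose (6 and 1 adjusted over the list alone; adjusted p = 0.019; adjusted p = 0.078 with an estimated correlation), and at 20 h the list did not pass (adjusted p = 0.2). MCL1 changed by -0.18 at 2 h, 0.03 at 5 h (adjusted p = 0.55) and 0.21 ± 0.04 at 20 h.

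Ribosome biogenesis genes fell with romidepsin, 34 of 40 at 5 h (camera adjusted p = 2.8e-20) and 39 of 40 at 20 h (1.4e-25), also adjusted over the list alone, with none higher. MYBBP1A reached -3.03 ± 0.06 and MRTO4 -3.04 ± 0.07 at 20 h. At 20 h 39 of 43 DNA replication genes fell and 1 rose, also adjusted over the list alone (camera adjusted p = 2.6e-14), with TYMS at -3.41 ± 0.07. In the same contrast 28 of 33 mitosis genes fell and 2 rose, also adjusted over the list alone (1.6e-09; adjusted p = 0.076 with an estimated correlation), with FOXM1 at -2.03 ± 0.05. Integrated stress response genes fell at 2 h, 10 of 29 against 3 higher (12 and 3 adjusted over the list alone; adjusted p = 6.3e-07), and at 5 h, 15 against 3 (16 and 3; 1.4e-05). The medians were -0.10 and -0.22 but the means 0.04 and 0.00. At 20 h 20 fell and 6 rose, also adjusted over the list alone (1.4e-04; adjusted p = 0.07 with an estimated correlation). SLC7A5, an amino acid transporter, reached -3.54 ± 0.05 at 20 h, while the stress factor ATF3 rose by 3.16 ± 0.09.

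Interferon-stimulated genes rose with romidepsin, 12 of 31 against 1 lower at 5 h (camera adjusted p = 2.8e-05) and 26 against 3 at 20 h (1.5e-04), also adjusted over the list alone, with OASL at 5.35 ± 0.13 at 20 h. Of 13 MHC class II genes 11 rose and 0 fell at 20 h, also adjusted over the list alone (camera adjusted p = 0.0019), with a median of 3.83, or 3.11 at the bound, and HLA-DRA at 2.47 ± 0.08. Neuronal genes rose at 20 h, 14 of 16 against 1 lower, also adjusted over the list alone (2.5e-05), with a median of 5.74, or 4.45 at the bound, and SYT11 at 9.82 ± 0.11. TUBB3 rose by 1.88 ± 0.52 at 2 h (adjusted p = 0.01), 2.65 ± 0.46 and 7.85 ± 0.22, to 37.8 ± 1.10 CPM (SD, n = 2). Genes at 0 counts in DMSO included COL1A1, a collagen, at least 430-fold higher, and SPANXN3 at least 314-fold higher at 20 h. The 3 metallothioneins rose at 20 h, also adjusted over the list alone, with MT2A at 6.92 ± 0.16.

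At 2 h with romidepsin the chaperone HSPA1B rose by 2.08 ± 0.10 and HSPA1A by 1.85 ± 0.31, which reached 1.94 ± 0.30 and 2.59 ± 0.28 at 5 and 20 h. Heat shock genes passed at 2 h, 6 of 21 higher and 2 lower (7 and 3 adjusted over the list alone; adjusted p = 1.7e-04; adjusted p = 0.14 with an estimated correlation). At 20 h 13 were lower and 7 higher, also adjusted over the list alone (0.011; adjusted p = 0.29 with an estimated correlation). Among single genes, OSM changed by -1.53 ± 0.22 and the zinc finger factor KLF11 by -1.53 ± 0.12 at 2 h. At 5 h PCDH18, a protocadherin, rose by 4.14 ± 0.25 and ETV1 by 2.76 ± 0.18, and PLD6 changed by -2.24 ± 0.12. At 20 h MGAT3 changed by -5.26 ± 0.07 and WDR72 by -5.24 ± 0.09.

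In all, 743, 2734 and 8095 genes were higher and 968, 3464 and 6271 lower with romidepsin, and 102, 946 and 5629 rose and 37, 136 and 2830 fell at least 2-fold. Fewer genes passed at 2 h with any 1 library left out. Higher genes numbered 338 and 373 without DMSO replicate 1 and 2 and 371 and 380 without romidepsin 2 h replicate 1 and 2, and lower genes 562 without romidepsin 2 h replicate 1. At 2 h the call of PRDM1 ended in some of these fits (-0.15 without DMSO replicate 1, -0.16 without DMSO replicate 2, -0.15 without romidepsin 2 h replicate 1). So did those of HDAC6 (-0.17 and -0.23 without DMSO replicate 1 and 2, -0.14 without romidepsin 2 h replicate 2) and TUBB3 (1.38 without DMSO replicate 1, 1.68 without romidepsin 2 h replicate 2). At 5 h the calls of CDKN1A (-0.14 and -0.18 without DMSO replicate 1 and 2, -0.13 without romidepsin 5 h replicate 1) and HDAC6 (-0.17 without DMSO replicate 1, -0.18 without romidepsin 5 h replicate 2) ended too. With library size as the only scaling the median of all genes moved from 0.02 to 0.14 at 5 h and from 0.22 to 0.46 at 20 h. The higher share of calls moved from 43.4% to 65.6% at 2 h and from 44.1% to 71.3% at 5 h (30.7% at 2 h with DESeq2). With that scaling PRDM1 and HDAC6 at 2 h (-0.09 and -0.14) and CDKN1A, IKZF1 and HDAC6 at 5 h (-0.02, -0.07 and -0.05) no longer passed, whereas MCL1 at 5 h did (0.16).

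**Figure D2:**
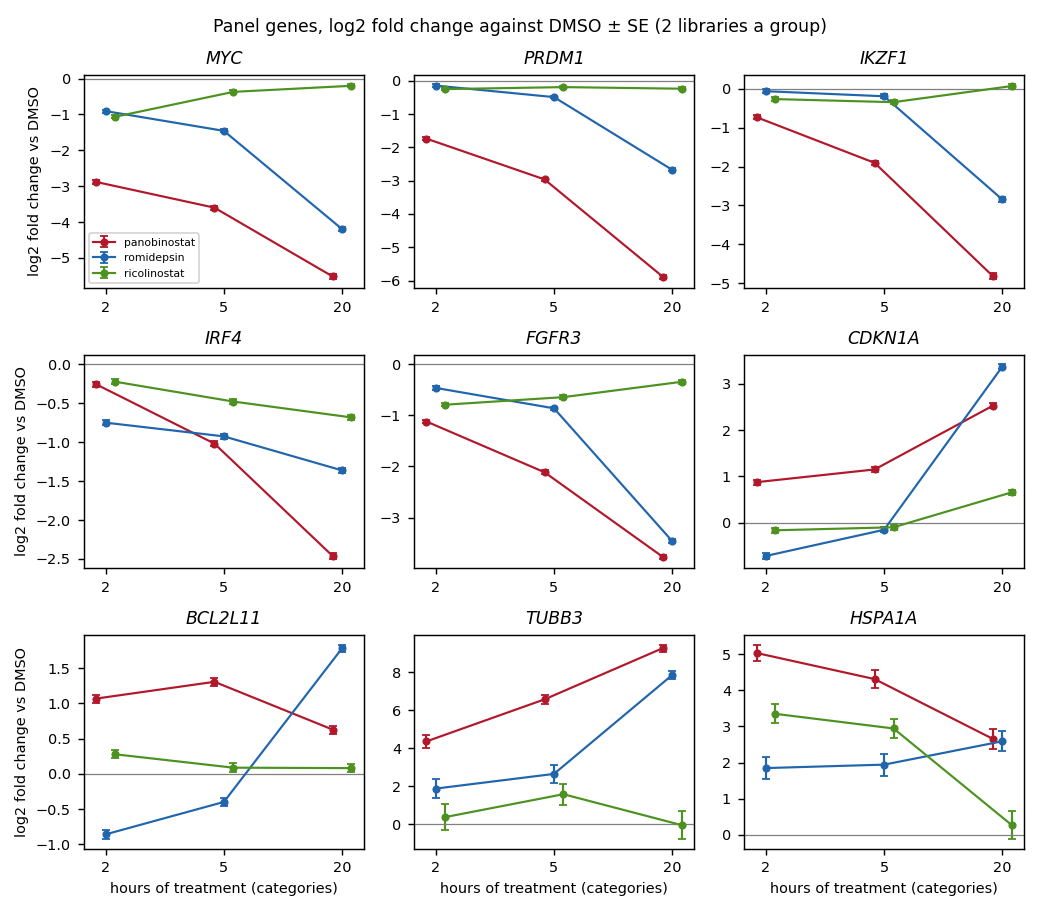
Log2 fold change against DMSO (points) with its SE (bars) of 9 genes of the fixed panel at 2, 5 and 20 h of each inhibitor, n = 2 libraries per group. MYC reaches -5.52 with panobinostat, -4.20 with romidepsin and -0.20 with ricolinostat at 20 h, and CDKN1A 2.52, 3.36 and 0.66.

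The comparison of ricolinostat with DMSO asks the question for an inhibitor described as selective for HDAC6. MYC changed by -1.07 ± 0.04, -0.37 ± 0.04 and -0.20 ± 0.04 at 2, 5 and 20 h, to 382 ± 5.38 CPM at 20 h (SD, n = 2). HSPA1B rose by 3.47 ± 0.09 and 2.96 ± 0.09 at 2 and 5 h and HSPA1A by 3.35 ± 0.26 and 2.94 ± 0.27, with 0.27 ± 0.38 at 20 h (adjusted p = 0.66). HDAC6 itself changed by -0.44, -0.49 and 0.25 ± 0.06, and HDAC1 by 0.08 (adjusted p = 0.15), 0.21 and 0.02 ± 0.04 (adjusted p = 0.77).

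Of the 29 plasma cell and myeloma genes 21, 25 and 19 fell and 0, 0 and 4 rose with ricolinostat at 2, 5 and 20 h (21, 26 and 19 lower and 2, 0 and 4 higher adjusted over the list alone). Camera gave adjusted p = 6.2e-16, 4.0e-18 and 2.1e-08, with the call at 20 h lost (adjusted p = 0.057 with an estimated correlation). FGFR3 changed by -0.79, -0.64 and -0.34 ± 0.03, CCND2 by -0.69, -0.69 and -0.23, IRF4 by -0.22, -0.48 and -0.68 ± 0.03, and PRDM1 by -0.25, -0.19 and -0.23 ± 0.04. NSD2 changed by -0.31, -0.19 and 0.16 ± 0.03, and IKZF1 by -0.26 and -0.34, with 0.07 at 20 h (adjusted p = 0.27). CDKN1A was at -0.16 ± 0.06 at 2 h (adjusted p = 0.022), -0.09 at 5 h (adjusted p = 0.21) and 0.66 ± 0.05 at 20 h. BCL2L11 rose by 0.28 ± 0.06 at 2 h and was at 0.09 and 0.08 at 5 and 20 h (adjusted p = 0.28 and 0.33). MCL1 changed by 0.46, -0.09 (adjusted p = 0.046) and -0.26 ± 0.04, and TUBB3 was at 0.38 ± 0.67 (adjusted p = 0.74), 1.58 ± 0.55 (0.016) and -0.04 ± 0.72 (adjusted p = 1).

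Heat shock genes rose with ricolinostat at 2 h, 14 of 21 against 2 lower (camera adjusted p = 1.6e-06), and at 5 h, 12 against 1 (2.1e-06), each lost with adjusted p = 0.07 with an estimated correlation. At 20 h 15 fell and 0 rose (4.5e-14). These numbers were the same adjusted over the list alone. HSP90AA1 was at -0.82 ± 0.03 at 20 h, and HSPA8 went from 0.79 ± 0.03 at 2 h to -0.82 ± 0.03. Sterol synthesis genes rose at 2 h, 17 of 24 against 2 lower (19 and 4 adjusted over the list alone; camera adjusted p = 4.9e-08), and at 5 h, 16 against 3, also adjusted over the list alone (3.5e-04; adjusted p = 0.07 with an estimated correlation). They fell at 20 h, 15 against 1 higher (18 and 1 adjusted over the list alone; 4.3e-08). SQLE, squalene epoxidase, rose by 0.83 ± 0.05 at 2 h. Of 28 genes of the unfolded protein response, 15 rose and 1 fell at 2 h, also adjusted over the list alone (camera adjusted p = 0.0019; adjusted p = 0.18 with an estimated correlation). At 20 h 23 fell and 1 rose, also adjusted over the list alone (1.9e-15), with HSPA5, the chaperone BiP, at -0.60 ± 0.04.

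Autophagy and lysosome genes rose with ricolinostat at 2 h, 15 of 27 against 1 lower (16 and 1 adjusted over the list alone; camera adjusted p = 1.1e-06), and 5 h, 18 against 1, also adjusted over the list alone (3.1e-07). ULK1, the kinase that starts autophagy, rose by 0.93 ± 0.06 and 1.05 ± 0.06. At 20 h 13 rose and 1 fell, also adjusted over the list alone (0.013; adjusted p = 0.18 with an estimated correlation). Ribosome biogenesis genes fell at 20 h, 38 of 40 against 1 higher (39 and 1 adjusted over the list alone; camera adjusted p = 1.3e-37), with DDX21 at -0.84 ± 0.04. So did 36 of 43 DNA replication genes, with 0 higher (39 and 0 adjusted over the list alone; 1.5e-21), with UHRF1 at -0.77 ± 0.05. Integrated stress response genes fell at 20 h, 21 of 29 against 2 higher (22 and 3 adjusted over the list alone; 6.5e-17), with SLC7A5 at -1.34 ± 0.04. At 5 h 14 fell and 3 rose (15 and 3 adjusted over the list alone; 1.3e-05). Proteasome subunits fell at 20 h, 25 of 31 with none higher (27 adjusted over the list alone; 3.5e-12; adjusted p = 0.11 with an estimated correlation). Interferon-stimulated genes rose at 20 h, 14 of 31 against 3 lower (15 and 3 adjusted over the list alone; 1.3e-04), with STAT2 at 0.95 ± 0.06.

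Mitosis genes passed with ricolinostat at 5 h, 14 of 33 lower and 6 higher (15 and 7 adjusted over the list alone; adjusted p = 0.024; adjusted p = 0.46 with an estimated correlation). They did not pass at 2 h (adjusted p = 0.064) or 20 h (0.73). Neuronal genes did not pass at any time (adjusted p = 0.9, 0.9 and 0.2), although MAP2, a microtubule protein of neurons, rose by 2.62 ± 0.16 at 20 h. Single rises included CTTNBP2NL at 2 h, 3.56 ± 0.27, and 5 h, 3.47 ± 0.28. At 20 h they included APLP1, 2.71 ± 0.23, the actin-severing protein GSN, 2.57 ± 0.17, and CYP1A1, a cytochrome P450, 2.44 ± 0.19. Falls included LRRC14B, -2.20 ± 0.20 at 2 h and -2.15 ± 0.20 at 5 h, and AJAP1, -2.09 ± 0.18 at 20 h, and CCR1 was at -2.03 ± 0.05 at 2 h.

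In all, 3543, 3935 and 3082 genes were higher and 3049, 3205 and 3432 lower with ricolinostat, of which 514, 722 and 984 rose and 572, 482 and 122 fell at least 2-fold. With library size as the only scaling the median of all genes at 20 h moved from 0.03 to 0.13, and the higher share of calls from 47.3% to 66.2%. The mitosis call at 5 h then ended (adjusted p = 0.062), while the list passed as lower at 2 h (adjusted p = 0.041) and as higher at 20 h (adjusted p = 0.043). In the same setting MCL1 at 5 h did not pass (-0.06), and IKZF1, BCL2L11 and HDAC1 at 20 h did (0.17, 0.18 and 0.12). Without 1 library, higher genes numbered 2238 and 2299 at 2 h (ricolinostat 2 h replicate 1 and 2) and 2466 at 5 h (ricolinostat 5 h replicate 1). The higher share of calls then moved from 53.7% to 41.1% and 43.5% at 2 h and from 55.1% to 37.9% at 5 h, and with DESeq2-type size factors to 45.7% and 46.3%. Calls ended for CDKN1A at 2 h (-0.16 without DMSO replicate 1, -0.19 without ricolinostat 2 h replicate 2), and BCL2L11 at 2 h (0.17 without ricolinostat 2 h replicate 1), and for HDAC1 at 5 h (0.08 without ricolinostat 5 h replicate 1) and TUBB3 at 5 h (1.06 without DMSO replicate 1, 1.56 and 1.48 without ricolinostat 5 h replicate 1 and 2). CDKN1A at 5 h passed without ricolinostat 5 h replicate 2 (-0.23) and mitosis genes at 2 h without DMSO replicate 1 (adjusted p = 0.021).

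**Figure D3:**
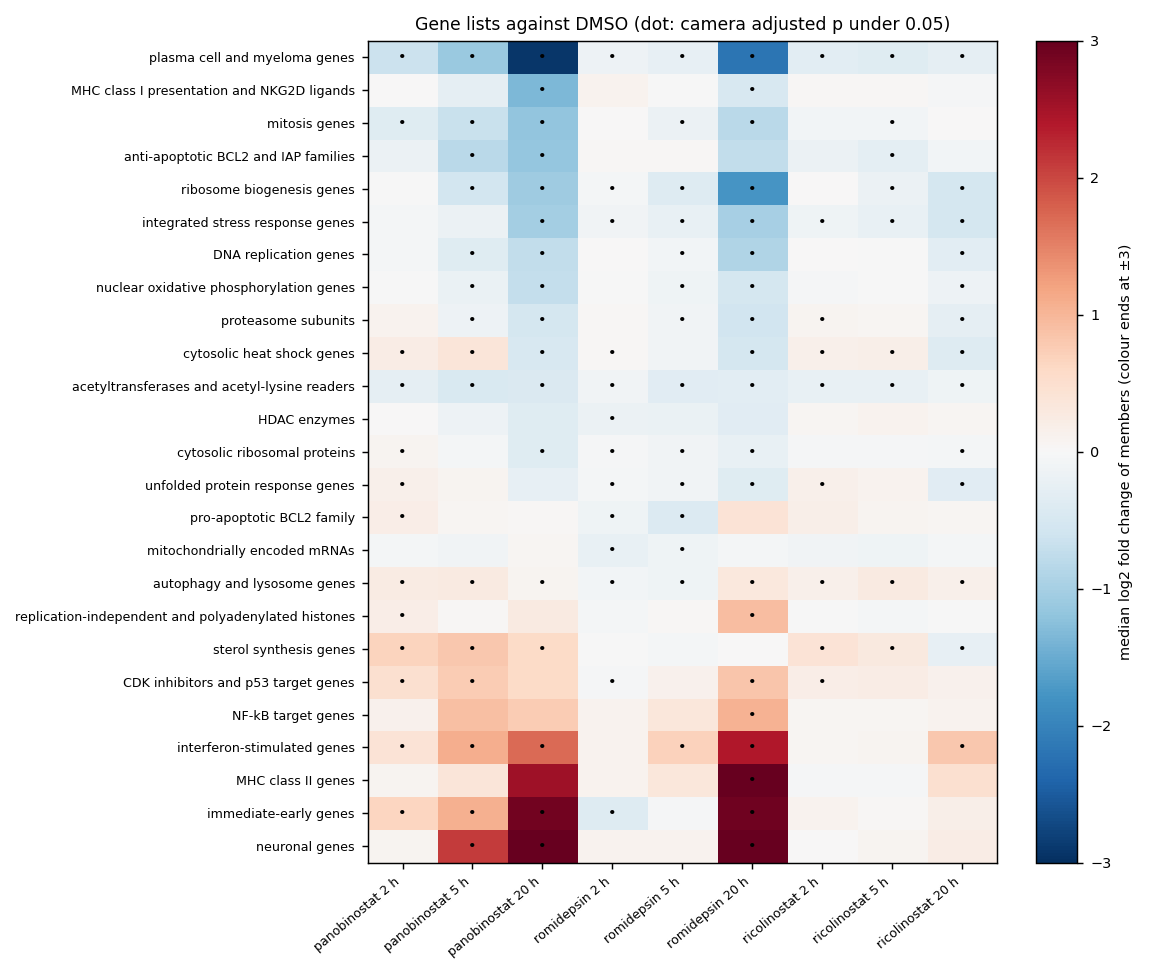
Median log2 fold change of gene lists (rows) against DMSO for each inhibitor and time (columns), with colours ending at -3 and 3. Only lists with camera adjusted p below 0.05 in any contrast with DMSO are drawn. Genes at 0 counts in a group were taken at their bound. Dots mark camera adjusted p below 0.05. Plasma cell and myeloma genes lie at -2.92 with panobinostat and -2.20 with romidepsin at 20 h, and at -0.27 with ricolinostat.

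Calls were shared between inhibitors beyond the number expected from independent calls. Panobinostat and ricolinostat at 2 h had 2904 genes higher and 2400 lower in both, where 736 and 553 were expected, and panobinostat and romidepsin at 20 h had 6975 and 5470, where 3306 and 2026 were expected. Simulations of unchanged groups that share the DMSO libraries gave at most 2.2 such genes per direction, as a mean of 5, in any pair and time. Across genes, which are not independent replicates, the fold changes had a covariance of 0.667 and 5.33 in these pairs, against 0.2497 and 0.2424 simulated (r = 0.586 and 0.932, simulated 0.491 and 0.504). On log2(CPM + 0.5) values r was 0.785 and 0.912 with the DMSO libraries shared. It was 0.643 and 0.892, with covariances of 0.141 and 1.44, when each inhibitor was set against its own DMSO library, as a mean of both assignments. Panobinostat and romidepsin at 2 h shared 479 higher and 536 lower genes (expected 154 and 175), with 233 and 266 higher in both without DMSO replicate 1 and 2. Their covariance at 2 h was 0.434 against 0.249 simulated (r = 0.429, simulated 0.484). On log2(CPM + 0.5) values r fell from 0.346 with shared to 0.182 with separate DMSO libraries, with a covariance of 0.0270. Romidepsin and ricolinostat shared 455 higher and 505 lower at 2 h (expected 126 and 141; 225 and 252 higher in both without DMSO replicate 1 and 2), and 2215 and 2752 at 20 h (expected 1190 and 1027). At 5 h the pairs shared 1785 and 2379 (panobinostat and romidepsin), 2957 and 2657 (panobinostat and ricolinostat), and 1403 and 1692 genes. The simulated counts leave out the effects and the counts expected from independent calls leave out the shared DMSO libraries, so the excess of shared calls over either does not measure a shared effect.

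Panobinostat and romidepsin, which differ in structural class, were compared at the same dose and time. At 2 h MYC was higher with romidepsin by 1.98 (95% interval 1.88 to 2.07; adjusted p = 7.6e-59), and the difference was 2.14 (2.03 to 2.25) at 5 h and 1.32 (1.17 to 1.47) at 20 h. CDKN1A was lower with romidepsin at 2 h, -1.59 (-1.70 to -1.48), and higher at 20 h, 0.84 (0.75 to 0.93), as was BCL2L11, -1.93 (-2.05 to -1.81) and 1.15 (1.05 to 1.26). HSPA1A was lower with romidepsin at 2 h, -3.18 (-3.56 to -2.80), and at 20 h the difference was -0.07 (-0.46 to 0.32; adjusted p = 0.83). HDAC1 did not differ past the threshold at 2, 5 or 20 h: -0.04 (-0.13 to 0.04), 0.05 (-0.04 to 0.14) and 0.04 (-0.04 to 0.12).

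Of the 29 plasma cell and myeloma genes 20, 23 and 23 were higher and 2, 2 and 2 lower with romidepsin than with panobinostat at 2, 5 and 20 h (20, 23 and 24 higher adjusted over the list alone). The camera values were adjusted p = 1.4e-11, 7.3e-17 and 6.4e-20. Mitosis genes were higher, 25, 28 and 27 of 33 against 0, 2 and 0 lower (25, 29 and 27 higher adjusted over the list alone; 8.8e-11, 1.7e-11 and 1.2e-12). Sterol synthesis genes were lower, 18, 17 and 15 of 24 against 2, 4 and 3 higher (19, 18 and 15 lower adjusted over the list alone; 5.4e-11, 3.5e-07 and 9.1e-08). At 20 h ribosome biogenesis genes were lower, 33 of 40 against 2 higher, also adjusted over the list alone (3.9e-16), while MHC class I genes were higher, 15 of 19 against 1 lower (16 and 1 adjusted over the list alone; 7.4e-11). These list calls were kept with an estimated correlation. Single differences included CCR2 at 2 h, 2.53 ± 0.15, SLC2A4 at 2 h, -5.62 ± 0.34, BAIAP3 at 5 h, -6.54 ± 0.25, P2RY6, a nucleotide receptor, at 20 h, 5.59 ± 0.08, and CD28 at 20 h, 3.97 ± 0.11. In all 3624, 5188 and 4907 genes were higher and 4154, 5431 and 3835 lower with romidepsin. The higher share at 20 h moved from 56.1% to 48.5% with library size as the only scaling.

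Ricolinostat and panobinostat are both hydroxamic acids, given at 100 and 10 nM. MYC was higher with ricolinostat by 1.82 (95% interval 1.72 to 1.92) at 2 h and 5.31 (5.19 to 5.43) at 20 h. At 2 h IRF4 and HDAC6 did not differ past the threshold, 0.03 (-0.03 to 0.10; adjusted p = 0.59) and -0.04 (-0.17 to 0.08; adjusted p = 0.73). Immediate-early genes were lower with ricolinostat at 2 h, 20 of 27 against 3 higher (21 and 3 adjusted over the list alone; camera adjusted p = 3.9e-16). At 5 h 21 were lower and 3 higher (21 and 4 adjusted over the list alone; 1.7e-07), and at 20 h 22 and 5, also adjusted over the list alone (3.3e-06). Plasma cell and myeloma genes were higher, 17, 22 and 26 of 29 against 1, 3 and 3 lower (17, 23 and 26 higher adjusted over the list alone; 1.2e-13, 1.2e-17 and 3.2e-18). So were mitosis genes, 23, 27 and 31 of 33 with none lower (25, 27 and 31 adjusted over the list alone; 1.6e-15, 1.7e-15 and 4.4e-16). Neuronal genes were lower at 5 h, 12 of 16 with none higher (12 and 1 adjusted over the list alone; 4.5e-05), and 20 h, 14 of 16 against 1, also adjusted over the list alone (7.5e-06). These list calls, too, were kept with an estimated correlation. Differences in single genes included SYT11 at 2 h, -4.32 ± 0.24, and 5 h, -6.76 ± 0.13, TASL at 20 h, 9.55 ± 0.19, and EPPK1, which encodes epiplakin, at least 2039-fold lower with ricolinostat at 20 h. In all 2063, 4932 and 6714 genes were higher and 1952, 4921 and 7704 lower. The higher share at 5 h moved from 50.1% to 40.7% with library size as the only scaling. At 2 h higher genes numbered 1368 without panobinostat replicate 1 and 1221 and 1317 without ricolinostat replicate 1 and 2, and lower genes 1252 without ricolinostat replicate 2. The median difference of all genes at 20 h was -0.16, and -0.36 with library size as the only scaling.

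Ricolinostat and romidepsin, at 100 and 10 nM, differed in MYC by -0.16 (95% interval -0.25 to -0.07; adjusted p = 0.003) at 2 h and by 3.99 at 20 h. CDKN1A did not differ past the threshold at 5 h, 0.05 (-0.06 to 0.17; adjusted p = 0.53), and was lower with ricolinostat by -2.71 at 20 h. HSPA1A was higher with ricolinostat at 2 h, with a 95% interval of 1.08 to 1.91, and lower at 20 h, -2.31. Autophagy and lysosome genes were higher with ricolinostat at 2 h, 19 of 27 against 1 lower (20 and 1 adjusted over the list alone; camera adjusted p = 8.4e-11), and 5 h, 21 against 0 (21 and 1; 4.9e-13). So were sterol synthesis genes, 15 of 24 against 2 lower at both times (17 and 15 higher adjusted over the list alone; 2.0e-09 and 6.3e-07). Heat shock genes were higher at 5 h, 17 of 21 against 1 lower (18 and 1 adjusted over the list alone; 9.4e-10). At 20 h ribosome biogenesis genes were higher, 38 of 40 against 1 lower (7.6e-20), as were plasma cell and myeloma genes, 24 of 29 against 4 (1.4e-17), and mitosis genes, 30 of 33 against 0 (1.3e-12). At 20 h immediate-early genes, 22 of 27 against 2 higher (1.8e-12), and neuronal genes, 13 of 16 against 1 (5.8e-06), were lower, the same numbers adjusted over the list alone. All of these list calls between ricolinostat and romidepsin were kept with an estimated correlation. Single differences included PER1, a clock gene, at 2 h, 1.94 ± 0.07, PCDH18 at 5 h, -2.45 ± 0.21, and MGAT3 at 20 h, 5.37 ± 0.07. In all 3478, 4021 and 6108 genes were higher and 2729, 3054 and 6930 lower with ricolinostat. With library size as the only scaling the higher share of calls moved from 56.0% to 44.7% at 2 h and from 56.8% to 41.1% at 5 h, and the median of all genes at 20 h from -0.11 to -0.24. At 5 h that share was 47.7% without ricolinostat 5 h replicate 1.

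Successive times of an inhibitor were compared to follow each response; time on the drug goes with time in culture, since no DMSO group of matched time is labelled. With panobinostat EPPK1 rose by 6.42 ± 0.35 and DHRS2, a dehydrogenase, by 4.68 ± 0.21 between 2 and 5 h, while PTPN7 changed by -2.73 ± 0.10. Between 5 and 20 h TENM1 rose by 7.11 ± 0.25 and POU2AF1 changed by -6.36 ± 0.08. With romidepsin ETV1 rose by 1.85 ± 0.16 between 2 and 5 h, and between 5 and 20 h CCR2 changed by -5.48 ± 0.21. With ricolinostat HK1, a hexokinase, rose by 1.26 ± 0.16 between 2 and 5 h, and between 5 and 20 h LRRC14B rose by 3.07 ± 0.20 while HSPA1B changed by -2.92 ± 0.10. Higher and lower genes numbered 4147 and 4643 between 2 and 5 h and 5754 and 6049 between 5 and 20 h with panobinostat, 1760 and 2493, and 6995 and 6157 with romidepsin, and 1401 and 1798, and 3610 and 4335 with ricolinostat. With library size as the only scaling the higher share between 2 and 5 h moved from 47.2% to 62.7% with panobinostat, 41.4% to 65.0% with romidepsin and 43.8% to 60.6% with ricolinostat, and between 5 and 20 h of panobinostat from 48.8% to 60.6%. The median of all genes was then 0.17 in place of 0.04 (panobinostat 2 to 5 h), 0.23 in place of 0.05 (5 to 20 h) and 0.20 in place of 0.09 (romidepsin 5 to 20 h). Without 1 library, lower genes between 2 and 5 h of romidepsin numbered 1534 (2 h replicate 2) and 1578 (5 h replicate 2). With ricolinostat higher genes numbered 765, 751, 901 and 810 (2 h replicate 1 and 2, 5 h replicate 1 and 2) and lower genes 1065 (2 h replicate 1). Between 5 and 20 h of ricolinostat the higher share moved from 45.4% to 55.2% without 5 h replicate 1 and to 54.9% with library size as the only scaling.

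Genes with 0 counts in both DMSO libraries enter the test only through their counts in other groups, so that the share of them that rose is set largely by the filter. Of the 1137 that were tested, 134, 559 and 1113 rose with panobinostat at 2, 5 and 20 h, 17, 103 and 1064 with romidepsin and 41, 62 and 92 with ricolinostat. Of these genes 1040 rose at 20 h with both panobinostat and romidepsin. Protein-coding genes among them numbered 487, 475 and 41 at 20 h of panobinostat, romidepsin and ricolinostat, whereas 5488 protein-coding genes of the whole table had 0 counts in DMSO. In the highest of 5 bins of mean expression 28.3% of genes rose and 63.3% fell with panobinostat at 20 h, and in the lowest bin 54.6% rose and 4.58% fell. With romidepsin at 20 h these shares were 28.0% and 61.4%, and 49.98% and 3.08%, and with ricolinostat 15.0% and 47.0%, and 3.72% and 0.406%. In the highest bin 7.25% rose and 27.6% fell at least 2-fold with panobinostat at 20 h. These were 5.87% and 20.7% with romidepsin and 0.0716% and 0.0954% with ricolinostat. The shares rest on TMM scaling: with library size only, lower genes with ricolinostat at 20 h numbered 2242 in place of 3432. Genes of the lowest bin, too, pass the filter mainly through the groups where they are high, which favours rises there. Among markers of other cell types, 3 of 59 genes reached 1 CPM in DMSO, and 11, 10 and 4 at 20 h of panobinostat, romidepsin and ricolinostat.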

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

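The tests of time in culture and of other cell types for genes at 0 counts in DMSO were chosen only after the result was seen, as was the interval used to read the test of time in culture for genes that turned direction. For the latter genes library size as the only scaling was fixed beforehand as an alternative, and its use to weigh the scaling as an explanation was chosen after the result was seen.

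Effects of opposite direction, with the direct difference also past the threshold, were found between times of an inhibitor. Between 2 and 5 h, 5 and 20 h, and 2 and 20 h they numbered 288, 675 and 1314 genes with panobinostat, 24, 892 and 491 with romidepsin, and 35, 969 and 1392 with ricolinostat. Most were small: at least 2-fold in both directions were 9, 28 and 72 genes with panobinostat. With romidepsin these numbered 0, 35 and 19, and with ricolinostat 0, 22 and 47. The genes named next come from this smaller set. DUSP2 went from -2.00 ± 0.10 at 5 h to 3.38 ± 0.07 at 20 h of romidepsin (edgeR adjusted p of the difference 1.5e-78), HSPA8 from 1.32 ± 0.03 at 2 h to -1.14 ± 0.03 at 20 h of panobinostat (1.1e-82), and the chemokine CCL3 from -1.68 ± 0.20 at 2 h to 1.89 ± 0.15 at 20 h of ricolinostat (8.0e-34). Between inhibitors at 2, 5 and 20 h opposite effects numbered 272, 902 and 436 genes for panobinostat and romidepsin, where independent calls would give 336, 1772 and 5176. They numbered 79, 500 and 1314 for panobinostat and ricolinostat (1276, 2003 and 2397 expected), and 214, 678 and 832 for romidepsin and ricolinostat (272, 1069 and 2248 expected). At least 2-fold in both directions were 5, 21 and 12 genes for panobinostat and romidepsin. For panobinostat and ricolinostat these numbered 2, 24 and 100, and for romidepsin and ricolinostat 1, 5 and 39.

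Genes at 0 counts in DMSO rose in large numbers at 20 h, 1113 with panobinostat and 1064 with romidepsin. Background reads that reach nearly all genes are argued against. Of 5488 protein-coding genes at 0 in DMSO, 69.2% stayed at 3 counts or fewer over both panobinostat 20 h libraries. Of the same genes 207 reached 1 CPM there. With romidepsin and ricolinostat at 20 h 74.9% and 95.7% stayed at 3 counts or fewer. Genes above 3 counts numbered 1693, 1377 and 235 with panobinostat, romidepsin and ricolinostat. Background reads confined to part of the genes were not tested. Of the 1113 genes 87.3% were lower in ricolinostat than in panobinostat at 20 h, against 7704 of all 20957 genes tested. The same panobinostat libraries chose these genes, which favours that outcome, so this share does not decide on time in culture. Of the 5488 genes, chosen by DMSO counts alone, 207, 155 and 0 reached 1 CPM at 20 h of panobinostat, romidepsin and ricolinostat. For these genes the values argue against time in culture alone. Cells of the 6 types listed are argued against, since 11 of their 59 markers reached 1 CPM with panobinostat at 20 h, with COL1A1 at 34.1 ± 0.917 CPM (SD, n = 2) but COL1A2 and COL3A1 at no more than 0.0391 CPM. As a hypothesis found on the same data, panobinostat and romidepsin may raise transcripts of genes that are silent in these cells; cell types outside the lists were not tested.

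Panobinostat and ricolinostat moved 5304 genes alike at 2 h and 79 in opposite directions. Chance values of the shared DMSO libraries are argued against, since r across genes was 0.643 with each inhibitor set against its own DMSO library, as a mean of both assignments. For handling common to all 2 h harvests, the median romidepsin change in the shared direction over these genes was 0.06. That is a ratio of 0.139 to the ricolinostat median of 0.47. The panobinostat and ricolinostat libraries chose these genes, which favours a low ratio, so the ratio does not decide. Over all genes tested, with separate DMSO libraries, r was 0.182 for romidepsin with panobinostat and 0.175 with ricolinostat, below 0.643. These values, read after the result was seen, argue against such handling alone. As a hypothesis that was not tested, the pair may share an early response that is smaller with romidepsin at this dose. Romidepsin at 2 h did share 479 higher and 536 lower genes with panobinostat, and 455 and 505 with ricolinostat. The doses differ, and a processing batch common to the pair cannot be examined because the labels list the batch as unknown.

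Between 2 and 20 h of ricolinostat 1392 genes turned direction against the same DMSO libraries, 47 of them at least 2-fold in both directions. With library size as the only scaling the number was similar, 1306, but whether the same genes turned was not examined. The count therefore does not decide whether the scaling is a source. Time in culture against DMSO of another harvest time cannot be told apart from a turn of the response. Of these genes 48.5% (exact binomial 95% interval 45.8% to 51.2%) had the ricolinostat 20 h direction with panobinostat and with romidepsin at 20 h too (51.0% and 63.9% with each), below the 60.2% of all genes with 1 direction in the 3 inhibitors, but the DMSO harvest time is not given, and genes are not independent.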

How the results depend on the processing

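All alternatives were planned, and none was chosen after the result was seen. Counts of called genes stayed within 1.5 times under DESeq2-type size factors, a fit of the 2 compared groups alone and the replicate block, which moved 0 of 93 counts and correlations. Of 2022 named genes and contrasts, 2005 kept their direction and side of the threshold with DESeq2-type size factors, 1998 with the DESeq2 Wald test, 1983 with no filter, 2018 with the replicate block and 1958 with library size only, where 56 were lost. Apart from the fixed panel, these genes were chosen as the largest called changes, which favours that outcome. Among all genes called, 4433 of 6198 with romidepsin at 5 h kept their call and direction with library size only. With panobinostat at 2 h 8111 of 8152 did. Genes of low level were recovered less often: in the simulated data 58.2% of genes changed 2-fold were recovered, against 94.1% of those at 5 CPM or more. Genes that the filter removed count as not recovered, and depth was not varied. For results that changed below, the cause was not tested unless stated.

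With library size only, higher and lower genes numbered 1187 and 622 with romidepsin at 2 h and 4212 and 1699 at 5 h, lower genes 2242 with ricolinostat at 20 h and 1407 between 2 and 5 h of romidepsin, and 8 lists passed with romidepsin at 5 h. Of all genes called with TMM, 171 of 15329 with panobinostat at 20 h were called in the opposite direction with library size only. With romidepsin at 20 h 66 of 14366 were. Among the named genes direction turned for MT-ATP8 with panobinostat at 20 h (0.15, -0.15 with TMM). It also turned for MT-ND3 with romidepsin at 5 h (0.0172, -0.11 with TMM) and 20 h (0.0852, -0.15 with TMM). The ribosomal protein list turned upwards with romidepsin at 2 h and ricolinostat at 20 h, without passing, with signed -log10 adjusted p-values of 0.118 and 0.160.

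With an estimated correlation, lists passed in numbers of 5, 5 and 6 with panobinostat, 4, 5 and 7 with romidepsin and 3, 3 and 7 with ricolinostat at 2, 5 and 20 h, 7 and 9 in romidepsin minus panobinostat at 5 and 20 h, 6 and 5 in ricolinostat minus panobinostat at 5 and 20 h, and 4, 5 and 7 in ricolinostat minus romidepsin. Of 486 list tests, 137 lost their call. With fry, which does not compare a list with other genes, 20, 25 and 26 lists passed with panobinostat, 23 with romidepsin at 5 h, and 16 and 17 with ricolinostat at 2 and 5 h. Between inhibitors, fry called 23 in romidepsin minus panobinostat at 2 h, 25 and 24 in ricolinostat minus panobinostat at 5 and 20 h, and 18 and 21 in ricolinostat minus romidepsin at 2 and 5 h. By construction fry asks another question: the unfolded protein response list turned upwards in ricolinostat minus panobinostat at 20 h (signed -log10 adjusted p 1.33), as did the integrated stress response list in ricolinostat minus romidepsin at 2 h (1.52). With DESeq2 the correlation across genes was 0.929 for panobinostat and romidepsin at 20 h and 0.606 for panobinostat and ricolinostat at 2 h. With no filter, 9 genes at 0 in DMSO passed with romidepsin at 2 h, where more genes were tested.

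Leaving out each library in turn gave 338 to 380 higher and 562 to 806 lower genes with romidepsin at 2 h, and 2238 to 2757 and 2466 to 2879 higher genes with ricolinostat at 2 and 5 h. It gave 1221 to 1680 higher and 1252 to 1572 lower genes in ricolinostat minus panobinostat at 2 h, 1534 to 2190 lower genes between 2 and 5 h of romidepsin, and 751 to 901 higher and 1065 to 1915 lower genes between 2 and 5 h of ricolinostat. Without DMSO replicate 1 or 2, genes higher in both numbered 233 and 266 for panobinostat and romidepsin and 225 and 252 for romidepsin and ricolinostat at 2 h. Correlations across genes then rose to 0.598 and 0.624 at 2 h and 0.598 and 0.619 at 5 h for panobinostat and romidepsin. They rose to 0.686 and 0.704, 0.600 and 0.621, and 0.480 and 0.501 at 2, 5 and 20 h for panobinostat and ricolinostat, and to 0.627 and 0.652, 0.648 and 0.676, and 0.560 and 0.578 for romidepsin and ricolinostat. By construction a single shared control library carries more of its own error into both contrasts.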

Other observations

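Several gene groups fell outside the account above. Of 23 acetyltransferases and acetyl-lysine readers 16, 14 and 15 fell and 6, 5 and 4 rose with panobinostat at 2, 5 and 20 h (16, 14 and 15 lower and 7, 5 and 4 higher adjusted over the list alone). Camera gave adjusted p = 2.7e-05, 1.3e-04 and 0.0027 (adjusted p = 0.13, 0.18 and 0.27 with an estimated correlation). KAT6B was at -1.73 ± 0.07 at 2 h and the elongation inhibitor HEXIM1 at 2.68 ± 0.14 at 20 h. With romidepsin at 5 h 16 fell and 1 rose (17 and 1 adjusted over the list alone; adjusted p = 1.0e-09), a call kept with an estimated correlation. Of 11 HDAC genes, HDAC7 changed by -4.27 ± 0.07 and HDAC3 by 1.44 ± 0.07 with panobinostat at 20 h. The list passed with romidepsin at 2 h, with 3 lower and 0 higher (6 and 0 adjusted over the list alone; adjusted p = 0.0072; adjusted p = 0.057 with an estimated correlation). Of 14 polyadenylated histone genes 7 rose and 1 fell with panobinostat at 2 h, also adjusted over the list alone (adjusted p = 0.0025; adjusted p = 0.18 with an estimated correlation). With romidepsin at 20 h 9 rose and 2 fell, also adjusted over the list alone (0.016; adjusted p = 0.27 with an estimated correlation), with the linker histone H1-2 at 3.31 ± 0.09. Of 13 NF-kB targets 10 rose and 2 fell with romidepsin at 20 h (11 and 2 adjusted over the list alone; 0.031; adjusted p = 0.12 with an estimated correlation), with IER3 at 7.81 ± 0.19 and NFKB1 at -2.05 ± 0.08. The 17 tubulins did not pass in any contrast with DMSO, with 8 higher and 6 lower at 20 h of panobinostat (8 and 6 adjusted over the list alone; adjusted p = 0.2). Of 9 anti-apoptotic genes 6 fell and 0 rose with ricolinostat at 5 h, also adjusted over the list alone (adjusted p = 0.0048; adjusted p = 0.12 with an estimated correlation). BCL2 changed by -4.26 ± 0.09 with panobinostat and -2.81 ± 0.08 with romidepsin at 20 h.

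Of the 76 cytosolic ribosomal proteins 32 rose and 2 fell with panobinostat at 2 h (33 and 2 adjusted over the list alone; adjusted p = 0.033; adjusted p = 0.8 with an estimated correlation), a call that ended without DMSO replicate 2 (adjusted p = 0.206). They fell at 20 h, 65 against 3 higher, also adjusted over the list alone (adjusted p = 2.8e-07; adjusted p = 0.49 with an estimated correlation). The call at 20 h ended with library size as the only scaling (adjusted p = 0.118). With romidepsin 3, 48 and 56 fell and 0, 0 and 8 rose at 2, 5 and 20 h (0, 57 and 57 lower and 0, 0 and 9 higher adjusted over the list alone; adjusted p = 0.039, 1.8e-07 and 2.6e-04; adjusted p = 0.81, 0.48 and 0.66 with an estimated correlation). These calls ended with library size as the only scaling, where the list lay upwards at 2 h (adjusted p = 0.762, 0.377 and 0.762), and that at 2 h without DMSO replicate 1 (adjusted p = 0.0673). With ricolinostat at 20 h 26 fell and 3 rose (30 and 3 adjusted over the list alone; adjusted p = 0.0048; adjusted p = 0.74 with an estimated correlation), a call that ended, with the list upwards, with library size as the only scaling (adjusted p = 0.692). Of 13 mitochondrially encoded mRNAs 4 fell and 0 rose with romidepsin at 2 h (11 and 0 adjusted over the list alone; adjusted p = 5.3e-09; adjusted p = 0.2 with an estimated correlation). Of 8 measured early B cell markers 4 rose and 2 fell with panobinostat (adjusted p = 0.4) and 4 rose and 1 fell with romidepsin at 20 h (adjusted p = 0.2), also adjusted over the list alone. BCL6, a germinal centre repressor, went from 2.17 to 25.3 and 28.2 CPM with panobinostat and romidepsin at 20 h (means, n = 2), while MS4A1 had 0 counts in these groups. Markers that reached 1 CPM at 20 h of panobinostat, romidepsin and ricolinostat numbered 0, 0 and 0 of 13 for T and NK cells, 2, 1 and 0 of 11 for myeloid cells, 1, 1 and 1 of 9 for erythroid cells, 5, 4 and 3 of 10 for early B cells, 2, 3 and 0 of 9 for stromal cells and 1, 1 and 0 of 7 for epithelial cells. Of 3347 genes for long non-coding RNAs 395, 31 and 328 were lower and 251, 36 and 120 higher at 2 h of panobinostat, romidepsin and ricolinostat. At 20 h 579, 469 and 50 were lower and 1396, 1267 and 432 higher. Antisense genes, whose strand setting is unknown, held 0.295% of counts in DMSO and 0.476%, 0.429% and 0.375% at 20 h of panobinostat, romidepsin and ricolinostat.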
